A study of Arabidopsis thaliana with 41 samples.

How the data were processed

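RNA-seq libraries of embryos of 2 genotypes (wild type and val1) at 7 ages were analysed from the values the authors deposited. Per the labels, wild-type and val1 embryos were dissected in parallel by 2 people at low temperature on dishes of frozen water, and washed to remove endosperm. RNA was purified with an RNeasy kit and sequenced as paired-end 75-base reads. Per the submitters' processing notes, TAIR10, TopHat2 and StringTie were used; no versions or roles are given. The 41 libraries were grouped by genotype and age from the sample titles. Every title carries a replicate number. The value columns of 34 libraries were matched to a numbered sample, and 7 were matched to their group alone and are called unnumbered here. These are the 4 columns of days 8 and 12 marked as a replacement, 1 per genotype and day, for which no sample label says the number, and the 3 of val1 at day 17. The columns of val1 at day 17 bear numbers, which were left aside by choice because the names resemble those of day 7. Comparisons that use numbers therefore leave out val1 at day 17, and their averages and interactions cover 6 ages.

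The authors deposited FPKM values per assembled transcript, with the transcript length and a class code that relates each transcript to the reference. FPKM times length summed to the same total in every library, so the deposited FPKM values are relative to the reads assigned to the listed transcripts. The deposited transcript length, in bases, is a value of another kind and was used to recover reads. A second deposited sheet, named for counts, held values that were 99.9997% not whole and 53.1 to 76.4% zeros. From its values it is another quantification on an FPKM scale, and it was used as an alternative. Its values correlated with those of the first sheet at 0.704 to 0.749 for the same numbered library. The authors' daily log2 differences correlated at 0.992 to 0.9996 with those from the first sheet. For both genotypes at day 8 and wild type at day 12 it has a numbered column where the first sheet has a replacement, so these libraries may differ. The deposited comparison table gives the authors' log2 difference per day, their F score, and their p-value and adjusted p-value per transcript; its column names are those of a moderated F test, with the tool not stated. Only transcripts past the authors' threshold are in that table.

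Transcripts of the classes that share a structure with a reference gene were summed per gene: of 53988 transcripts, 52881 were assigned to 33544 genes, of which 32812 matched the locus tags of the reference table of assembly TAIR10.1, used for names and for gene neighbours alone. The other 1107 transcripts, with class codes for overlap, antisense or no reference gene, took 0.569 to 7.94% of the reads and were kept out of the comparisons. FPKM times length came in whole steps of a twelfth of a read for 100% of the low values (tolerance 0.02), with the size of a read set from the smallest value above 0 of each library. On that assumption the depth of the libraries was 8321306 to 51738641 reads, median 29731894. The series has 4 technical replicates, and how they were combined was not established from the values, so the depth is an estimate on that scale and the recovered reads are not whole. No gene listed at 0 in a single library held 5 FPKM or more in all the others.

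Libraries were scaled by a trimmed mean of log ratios, with 30% trimmed from the log ratio and 5% from the mean on each side, without weights. Genes with at least 1 FPKM in at least 2 libraries were tested, 18389 in all. Values were tested as log2(scaled FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with a trended prior, in 1 model with a mean for each of the 14 groups and 27 residual degrees of freedom. Contrasts were val1 minus wild type on each day and on average over days, the interaction of genotype and day, day 12 minus day 7 and day 17 minus day 12 in each genotype, and the differences of those intervals between genotypes. Adjusted p values are Benjamini-Hochberg over all genes tested, with calls at 0.05. The plan written before the data were examined named a count-based test; the values were FPKM, so limma was used. Sets were tested with camera at a preset correlation of 0.01 and again with the estimated correlation, adjusted over 14 lists. The lists, of embryo maturation regulators, VAL and Polycomb, storage proteins, oil body proteins, fatty acid and oil synthesis, LEA and desiccation, photosynthesis, cell cycle, abscisic acid, gibberellin, lipid mobilisation, seed coat and flavonoid, endosperm, and cold and handling genes, were also fixed before the data were examined, as were the model, the contrasts, the alternatives not said to be added, and the rule for named genes. Figures and tables were made with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

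The named-gene rule was: VAL1 first; for the average and development contrasts the 10 higher and 10 lower genes with the largest log2 difference among those called, with a log2 difference of at least 1, a mean log2 CPM of at least 1 and, for the average, the same sign on all 7 days; for each day the 3 higher and 3 lower genes by the same rule without the sign condition; for the interaction the 6 genes with the smallest p; and for each list up to 4 members with the smallest p, with every member of the embryo maturation and VAL and Polycomb lists. Of the embryo maturation list, bZIP53 and MYB115 were below the filter. The development contrasts in val1 name only some of the genes the rule gives, for length.

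Numbered libraries of the same day were checked for pairing before the blocked calls were seen, by the correlation of their deviations from the group means. Of 16 pairs with the same number, 15 correlated above 0.1 (median 0.443, highest 0.605, lowest 0.0743 for number 1 of day 15), against a median of -0.208 for different numbers. Deviations from a group mean cancel out within the group, so positive values for the same number push the others down. The negative median is therefore no separate support for pairing. Days 7, 10 and 13 have 3 pairs each, all above 0.1, so the numbers were taken as pairs there, and the labels' account of parallel dissection gives a source for it. Alternatives were other scalings, pseudocounts and filters, limma-voom on recovered reads, replicate blocks, each library left out in turn, a fit on the 2 groups alone and a minimum log2 difference of 1. Added after the data were examined were no scaling, pseudocounts 0.1 and 1, transcripts of the reference structure only, the second quantification, leaving out the 6 libraries in which ribosomal RNA took 2.63 to 13.5% of reads (0.42 to 1.57% in the others), the 34 numbered libraries only, and scaling without storage protein, oil body and LEA genes.

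The steps were tested on simulated data with known changes. For the average contrast, 88, 95.8, 100 and 100% of genes changed by a log2 of 0.5, 1, 2 and 4 were recovered, and for day 13, 30, 77.1, 95.9 and 95.8%, with 11 false calls among 17842 unchanged genes of the average contrast. The interaction gave 21 calls, although the simulated changes were the same on all days. Errors were drawn independently for each gene and library, and changes were balanced in sign. The false calls therefore do not carry over to data in which genes or paired libraries vary together.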

Results

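RNA was sequenced from developing embryos of wild-type Arabidopsis thaliana and of val1, a line mutated in VAL1 (AT2G30470, also named HSI2), which encodes a B3-domain transcriptional repressor. Embryos were 7, 8, 10, 12, 13, 15 and 17 days old. Each of the 14 combinations of genotype and age had 3 libraries, except wild type at day 17 with 2, which gave 41 libraries. The series design names 3 biological and 4 technical replicates. Depth estimated from the deposited FPKM steps ran from 8321306 reads in a val1 day 7 library to 51738641 in a val1 day 8 library, with a median of 29731894. Storage protein genes took 0.0892% of the reads in wild type at day 7 and 52.6% at day 13. Libraries of the same group correlated at 0.968 to 0.991. The first principal component of the 18389 genes tested held 67.0% of the variance and the second 20.8%, and the component that separated the genotypes held 2.32%. Differences below are on the log2(scaled FPKM + 0.5) scale, which understates the change of genes with low values, and come with the standard error (SE) and the Benjamini-Hochberg adjusted p of limma. Group levels are scaled FPKM, mean ± SD, with n = 3 unless stated.

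The level of VAL1 in every group shows whether the libraries carry the genotype they are named for. VAL1 was lower in val1 at every age. At day 7 it stood at 11.5 ± 1.53 in wild type and 1.42 ± 0.653 in val1, a log2 difference of -2.70 (SE 0.19, adjusted p = 2.86e-12). At day 17 it stood at 6.06 ± 0.51 in wild type (n = 2) and 2.56 ± 0.56 in val1, a log2 difference of -1.11 (SE 0.21, adjusted p = 0.000226). The mean level in val1 was thus 12.4% of wild type at day 7 and 42.2% at day 17, and the difference varied with age (interaction adjusted p = 0.000307). In deposited FPKM without scaling, the reference form of VAL1 at day 17 was at 1.71 in wild type and 0.322 in val1. The other assembled form was at 3.00 and 1.17, so the share at day 17 depended on the form and on the scaling. In wild type VAL1 reached 20.06 ± 0.39 at day 10. It rose from day 7 to day 12 by a log2 of 0.58, a value that was -0.65 with no scaling of the libraries, and fell by 1.45 from day 12 to day 17. Averaged over the 7 ages the log2 difference was -1.70 (SE 0.07, adjusted p = 4.16e-19). The highest val1 library, at day 10, had 7.20 and the lowest wild-type library, at day 17, had 5.70, so libraries of different ages overlapped between genotypes while those of the same age did not. The day 17 call was not kept with the second deposited quantification.

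**Figure D1:**
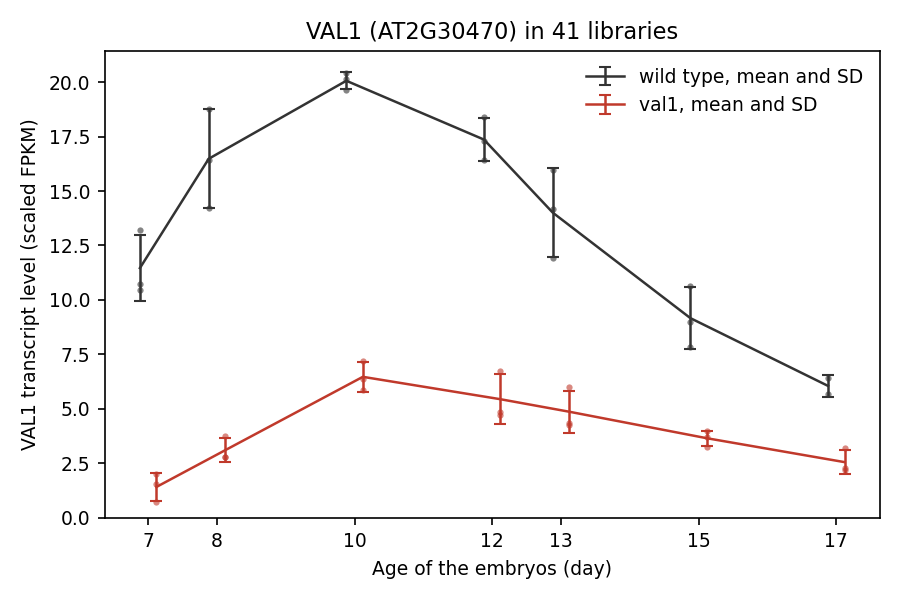
Scaled FPKM of VAL1 in each library (points) by age in days for wild type and val1, with lines and bars for the group mean and SD. Wild-type means ran from 20.06 at day 10 to 6.06 at day 17, and val1 means from 6.47 at day 10 to 1.42 at day 7.

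Development in wild type from day 7 to day 12 gives the background against which the mutant is read: which genes change as embryos pass into seed filling. In wild type 6615 genes rose and 7132 fell. The largest changes given here are those of called genes with a mean log2 CPM of at least 1. CRU3, a cruciferin storage protein, went from 28.3 ± 9.4 at day 7 to 1.97e+05 at day 12, a log2 rise of 12.67 (SE 0.72). The glycine-rich protein gene AT2G05580 rose by 12.77 (SE 0.35), CRU2 by 11.97, the cupin gene AT1G03890 by 11.80 and the AWPM-19-like gene AT1G04560 by 11.58. AT5G45690 rose by 11.10, TIP3;1, a vacuolar membrane channel of seeds, by 11.04, the thionin gene AT2G15010 by 11.04, AT1G05510 by 11.02 and GASA3 by 10.86. Among genes of that abundance RBCS3B, a small subunit of Rubisco, fell most at -6.73 (SE 0.41), followed by the arabinogalactan protein gene AGP31 at -6.08, the histone genes HTA11 at -5.92, AT1G09200 at -5.91, AT5G10400 at -5.68 and HTA13 at -5.64, the plastid ribosomal gene PSRP3/1 at -5.81, PSBQA of photosystem II at -5.71, AT4G20320 at -5.74 and ENODL3 at -5.63.

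By fixed list, all 13 storage protein genes rose from day 7 to day 12 in wild type (median log2 10.11, set test adjusted p = 3.04e-11), as did all 11 oil body genes (1.7e-09) and 16 of 20 LEA and desiccation genes (8.66e-08). All 33 cell cycle genes fell (median -4.29, 4.91e-19) and 42 of 46 photosynthesis genes fell (median -2.45, 1.06e-06). Of the 19 abscisic acid genes 11 rose and 4 fell (0.0186), and 8 of 11 lipid mobilisation genes rose (0.0128). The other lists did not pass the set test: embryo maturation regulators had 8 higher and 5 lower of 15, fatty acid and oil synthesis 12 and 7 of 27, gibberellin 6 and 4 of 12, seed coat and flavonoid 4 and 7 of 14, endosperm 0 and 3 of 4, VAL and Polycomb 5 and 5 of 12, and cold and handling 5 and 2 of 15, with set test adjusted p from 0.156 to 0.806. Adjusted over the list alone, the counts differed only for endosperm, with 1 higher and 3 lower. With an estimated correlation none of the 7 set calls held, with adjusted p = 0.0909 for cell cycle, 0.107 for storage and for oil body, 0.148 for abscisic acid, 0.197 for LEA and 0.504 for photosynthesis and for lipid mobilisation. With no scaling the median of all genes moved to -1.07 and 15.4% of 14583 calls were higher, against 48.1% of 13747 with scaling. The lipid mobilisation list then had 4 higher and 5 lower with a median of -0.45, and FUS3, AGL15, ABI4, HSL1, SWN, EMF2 and MFP2 changed sign.

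From day 12 to day 17 in wild type 6305 genes rose and 7131 fell. This comparison covers the passage into drying seed. The glycine-rich protein gene AT5G35660 rose by 13.11, AT1G68250 by 12.11 and the small heat shock gene HSP17.6A by 11.93 (SE 0.93). RAB18, a dehydrin that responds to abscisic acid, rose by 9.67 (SE 0.67), the LEA gene ATECP31 by 11, HSP17.4 by 10.39 and the LEA gene AT2G42560 by 10.08. The beta-glucosidase gene BGLU19 rose by 11.24, the metallothionein gene AtMT4b by 8.89 and AT3G10020 by 8.86. Among the falls were FAD3, which desaturates linoleic acid, at -9.34 (SE 0.58), the gibberellin synthesis gene GA20OX3 at -8.96, BZO1 and AOP3 of glucosinolate synthesis at -8.53 and -8.52, the light-harvesting gene LHB1B2 at -8.26 and the flavonol synthase gene FLS1 at -8.25. AT1G62500 was at -9.62, AT5G10580 at -8.37, AT1G55360 at -8.29 and AT1G62080 at -8.27.

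All 20 LEA and desiccation genes rose from day 12 to day 17 in wild type (median 6.94, set test adjusted p = 1.21e-10) and all 11 lipid mobilisation genes rose (2.94e-06). Of 27 fatty acid and oil synthesis genes 24 fell and 2 rose (median -5.29, 2.49e-09), of 46 photosynthesis genes 42 fell and 1 rose (median -5.46, 1.21e-10), and of 33 cell cycle genes 22 fell and 1 rose (0.0384). The other lists did not pass: embryo maturation regulators had 2 higher and 9 lower, storage proteins 1 and 6, oil body 5 and 2, abscisic acid 10 and 6, gibberellin 2 and 9, seed coat and flavonoid 2 and 7, cold and handling 2 and 9, VAL and Polycomb 2 and 5, and endosperm 0 and 0, where the median was 0 and the mean 0.04. Set test adjusted p ran from 0.106 to 0.781. Adjusted over the list alone every one of these counts was the same. With an estimated correlation none of the 5 calls held, at adjusted p = 0.325 for the first 4 and 0.675 for cell cycle. The median of all genes was -0.21 with limma-voom on recovered reads.

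The same 2 intervals in val1 show how much of development the mutant shared with wild type. From day 7 to day 12, 6612 genes rose and 7081 fell in val1. Of the wild-type calls, 5939 of the rises and 6522 of the falls were also called in val1 in the same direction (89.8% and 91.5%; independent lists would share 2379 and 2746), and 7 wild-type rises and 17 wild-type falls were called in the opposite direction. AT2G05580 rose by 12.81, CRU3 by 12.13, CRU2 by 11.42 and TIP3;1 by 10.30 in val1. RBCS3B was at -5.88, CP29, an RNA-binding protein of chloroplasts, at -5.47, PSBQA at -5.25 and the ferritin gene FER3 at -5.23. All 13 storage (set test adjusted p = 1.11e-10) and 11 oil body genes (1.26e-09) and 19 of 20 LEA genes (8.47e-09) rose, while all 33 cell cycle genes (1.09e-17) and 39 photosynthesis genes (3.65e-06) fell. Abscisic acid had 10 higher and 4 lower (0.042) and lipid mobilisation 7 higher (0.0331), and adjusted over the list alone these counts were the same. The other lists gave 0.0709 to 0.984. None of these 7 set calls held with an estimated correlation, at adjusted p = 0.118 to 0.484. With no scaling the median of all genes was -0.98 and 16.8% of 14406 calls were higher, against 48.3% of 13693 with scaling, lipid mobilisation had 3 higher and 6 lower and abscisic acid 8 and 8, and FUS3, WRI1, ABI4, AGL15, HSL1 and SWN changed sign.

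From day 12 to day 17, 6381 genes rose and 7408 fell in val1, with 5519 rises and 6272 falls shared with wild type (87.5% and 88.0% of the wild-type calls; independent lists would share 2188 and 2873) and 39 and 52 called in the opposite direction. AT5G35660 rose by 10.18, ATECP31 by 9.58, RAB18 by 9.33, HSP17.6A and BGLU19 by 8.98 each, and EM1, a LEA protein of the dry seed, by 8.34. The light-harvesting genes LHB1B2 and CAB3 were at -7.70 and -7.68, PLA2-ALPHA at -7.68, GA20OX3 and the acyl carrier gene ACP5 at -7.62 each and CHIL, a chalcone isomerase-like gene, at -7.41. All 20 LEA genes (set test adjusted p = 1.26e-10), all 11 lipid mobilisation genes (3.94e-06), 8 of 11 oil body genes (0.0315) and 11 of 19 abscisic acid genes (0.0246) rose, while 1 oil body and 4 abscisic acid genes fell. Falls covered 42 photosynthesis (2.71e-10), 24 fatty acid and oil synthesis (2.03e-07) and 30 cell cycle genes (5.23e-06), with 1, 2 and 1 higher. Adjusted over the list alone 43 photosynthesis genes fell and the other counts were the same. The other lists gave 0.11 to 0.949. None of the 7 set calls held with an estimated correlation, at adjusted p = 0.235 to 0.618. For storage proteins the median was 0.02 and the mean -0.11, and for endosperm both lay below 0 with the set test upward. With no scaling the median of all genes was -0.34 and 32.4% of 12280 calls were higher, against 46.3% of 13789, and ABI3 and FLC changed sign.

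The average difference between genotypes over the 7 ages is the mean of the daily differences, and a gene can pass it through a few days alone. In val1 3611 genes were higher and 2284 lower, and 341 of these 5895 differed by a log2 of at least 1. The second quantification gave 2823 genes in place of 5895. On every one of the 7 days 61 genes were called higher and 28 lower. AT1G02770, a gene of unknown function, differed most among genes with a mean log2 CPM of at least 1: it went from 0.621 ± 0.6 in wild type to 33.5 ± 2.7 in val1 at day 7 and from 2.31 ± 0.71 (n = 2) to 61.7 ± 8.9 at day 17, an average log2 difference of 5.09 (SE 0.09, adjusted p = 6.94e-30). AXR3, an Aux/IAA repressor of the auxin response, averaged 3.23 (SE 0.12, adjusted p = 2.21e-20): it was at 9.25 ± 0.64 in wild type and 48.9 ± 0.71 in val1 at day 10, and at 1.12 ± 0.66 and 48.6 ± 7.7 at day 13. RGF2, a peptide growth factor of the root meristem, averaged 3.04 (SE 0.16, adjusted p = 1.19e-16), with 2.24 ± 1.4 in wild type and 63.9 ± 6.8 in val1 at day 13. ADF5, an actin-depolymerizing factor, averaged 2.92 (SE 0.08, adjusted p = 9.6e-24) and stood at 6.12 ± 0.54 and 43.9 ± 2.2 at day 12. The RING finger gene AT5G60250 averaged 3.46, the zinc-binding dehydrogenase genes AT5G16980 and AT5G17000 3.31 and 2.84, the transporter-family genes AT4G04760 and AT3G05150 3.20 and 2.73, and the hydrolase gene AT5G02230 2.88, with adjusted p from 1.5e-31 to 3.09e-16. AT5G02230 was abundant in both genotypes, at 138 ± 22 and 504 ± 53 at day 12, while AT3G05150 was listed at 0 in all 3 wild-type libraries at day 15.

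Among genes lower in val1, ILA, a HEAT-repeat protein, averaged -3.13 (SE 0.10, adjusted p = 1.76e-22) and went from 508 ± 113 in wild type (n = 2) to 11.1 ± 2.9 in val1 at day 17, although it did not differ at day 7 (11.3 ± 0.85 and 8.19 ± 2.1). This difference lay in assembled ILA transcripts other than the reference form, since with only transcripts that match the reference structure the ILA average was -0.02 (adjusted p = 0.866). FLA7, a fasciclin-like arabinogalactan protein, averaged -2.16 (SE 0.15, adjusted p = 1.89e-13) and stood at 21.1 ± 0.94 and 1.87 ± 0.40 at day 8. XRCC4, which acts in the repair of DNA double-strand breaks, averaged -1.72 (SE 0.07, adjusted p = 1.72e-20), with 11.3 ± 0.56 and 3.20 ± 0.39 at day 7. The WD40 gene AT1G36070 averaged -1.80, the EF-hand gene AT3G10300 -1.63, the F-box gene AT3G59210 -1.49, MAPR2 of the progesterone-binding family -1.49, the jasmonate synthesis gene OPR3 -1.46 and the cystatin-like gene AT5G56910 -1.44, with adjusted p from 4.09e-20 to 1.16e-12.

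The fixed lists of the average comparison held few large changes. Of 33 cell cycle genes 21 were higher and none lower (23 and 1 adjusted over the list alone), with CDT1A at 0.38, MCM3 at 0.37, TSO2 at 0.40 and CYCD3;1 at 0.38. The set test gave adjusted p = 0.00208, and adjusted p = 0.907 with an estimated correlation. Of 15 embryo maturation regulators 6 were higher and 1 lower (7 and 1 adjusted over the list alone; set test 0.504). NF-YB6, a LEC1-like subunit of a CCAAT-binding factor, was higher by 1.29 (SE 0.15, adjusted p = 3e-08), AGL15 by 0.45, DPBF2 (bZIP67) by 0.35, BBM by 0.33, LEC1 by 0.25 and ABI4 by 0.21, and ABI5 was lower at -0.48. In the 34 numbered libraries, which leave out val1 at day 17 and so average 6 ages, DPBF2 was at -0.04. The differences of NF-YB6, AGL15, DPBF2, LEC1 and ABI4 varied with age (interaction adjusted p from 1.65e-05 to 0.0353), and those of BBM and ABI5 did not pass that test. Of the genes named from the cell cycle and the VAL and Polycomb lists, TSO2, CDT1A, MCM3, VAL1, FLC and FIE passed it (4.43e-06 to 0.0477). ABI3, LEC2, FUS3, WRI1, DOG1, EEL, HSFA9 and MYB118 did not pass the average comparison. In the VAL and Polycomb list 5 of 12 were higher and 2 lower (6 and 2 adjusted over the list alone; set test 0.656, median 0.10, mean -0.02): FLC, a repressor of flowering, by 0.58 (SE 0.05, adjusted p = 3.57e-12), CLF by 0.24, HSL1 (VAL2) by 0.23, FIE by 0.23 and SWN by 0.21, with VAL1 and VAL3 (-0.26) lower.

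Storage proteins had 4 of 13 higher on average, with the 2S albumin genes SESA4 at 1.27 (SE 0.17), SESA3 at 0.69 and SESA2 at 0.63, and oil body proteins 2 of 11. LEA and desiccation had 2 of 20 higher and 5 lower, with XERO1 at 0.93, PER1 at 0.65 and EM1 at -1.23. The differences of SESA4 and PER1 varied with age (interaction adjusted p = 1.93e-05 and 4.37e-12), so their averages do not stand for each day. Abscisic acid had 6 of 19 higher and 5 lower (6 and 6 adjusted over the list alone; median 0.05, mean 0.03, set test downward): CYP707A2, which breaks down abscisic acid, was higher by 1.23 (SE 0.08, adjusted p = 2.11e-14) but at -0.03 in the second quantification, while the phosphatases ABI2 and AHG1 were at -0.57 and -0.71. Gibberellin had 4 of 12 higher and 2 lower, with GA2OX8 at 1.3, GASA6 at 1.05 and the DELLA gene RGL2 at -0.69. Fatty acid and oil synthesis had 5 of 27 higher and 2 lower, with the elongase KCS18 (FAE1) at 0.71 and PDAT at -0.33. The KCS18 difference varied with age too (interaction adjusted p = 1.58e-05). So did those of CYP707A2, ABI2, AHG1, SESA3, SESA2, XERO1, EM1, ICL, GA2OX8, RBCS1B and RGL2 (interaction adjusted p from 1.06e-07 to 0.0434). Photosynthesis had 5 of 46 higher (3 adjusted over the list alone), with RBCS3B at 0.93 and RBCS1B at 0.80. Cold and handling had 5 of 15 higher and 1 lower, with TCH2 at 1.09, lipid mobilisation 2 of 11 higher and 1 lower, with ICL at 0.37 and LACS7 at -0.40, seed coat and flavonoid 2 of 14 higher, with MUM4 at 0.59 (median -0.01, mean 0.04), and endosperm none of 4. For the lists in this paragraph the set test gave adjusted p from 0.459 to 0.877 and the counts adjusted over the list alone were the same where not given.

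Some of these counts of the average comparison rested on few libraries or on the values used. Oil body genes numbered 6 without the unnumbered val1 library of day 8 and 1 without wild-type replicate 1 of day 17. Fatty acid and oil synthesis genes, 7 in both directions with all libraries, numbered 12 without wild-type replicate 3 of day 15, 13 without val1 replicate 2 of day 15 and 12 without val1 unnumbered library 2 of day 17. Photosynthesis genes numbered 8, 9 and 3 without wild-type replicate 3 of day 15, val1 replicate 2 of day 15 and wild-type replicate 1 of day 17, and lipid mobilisation genes 5 without val1 replicate 2 of day 15. Of the cell cycle genes 13 were higher and 1 lower without the 6 libraries with more ribosomal RNA, 7 were higher with limma-voom on recovered reads and 6 with the second quantification.

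Each daily comparison gives the difference between val1 and wild type at the same labelled age. The number of genes called grew from 597 at day 7 to 3260 at day 13, with 620 at day 8, 992 at day 10 and 1561 at day 12. It was 3246 at day 15 and 2870 at day 17. The second quantification gave 319, 270, 466, 784, 1499, 1563 and 1388 on the 7 days, and the 34 numbered libraries 397 at day 8 and 855 at day 12. With scaled libraries more genes were higher than lower in val1 on every day. With no scaling 24.7% of 2626 calls were higher at day 17, and more than 50% on each other day. In fits on the 2 groups of a day alone, which have fewer libraries, 79 of 189 daily calls of named genes did not pass and none changed sign.

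**Figure D2:**
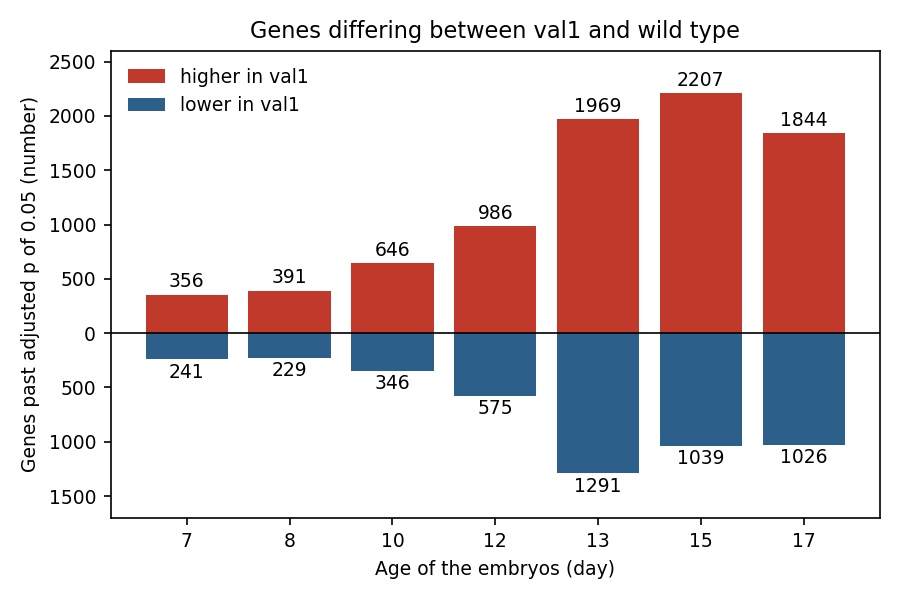
Number of genes higher and lower in val1 than in wild type by age in days, from limma on scaled libraries with adjusted p under 0.05. Higher genes ran from 356 at day 7 to 2207 at day 15, and lower genes from 229 at day 8 to 1291 at day 13.

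At day 7, 356 genes were higher and 241 lower in val1. PER1, a peroxiredoxin of seeds, was at 0.712 ± 0.46 in wild type and 20.6 ± 7.1 in val1, a log2 difference of 4.13 (SE 0.25, adjusted p = 8.34e-14). SESA4 was at 5.53 ± 1.9 and 102 ± 47, a difference of 4.03 (SE 0.44, adjusted p = 6.76e-08). AT1G02770 was higher by 5.07, and FLA7, VAL1 and AT3G59210 were lower at -2.75, -2.70 and -1.94. AT3G59210 was at -2.31 with adjusted p = 0.0652 in a fit on these 2 groups alone. Of 13 storage protein genes 5 were higher (6 adjusted over the list alone), among them SESA3 at 2.97, AT2G28490 at 1.62 and PAP85 at 1.23. The set test gave 1.77e-07, and adjusted p = 0.636 with an estimated correlation. Of 11 oil body genes 3 were higher, HSD5 by 1.42, ATS1 by 1.26 and AT2G25890 by 0.81 (set test 0.147, median 0, mean 0.24). PER1 and RAB28 (-0.78) were the LEA genes called, and ICL at 0.98, COR15B at 1.3 and VAL1 the genes called in their lists. Photosynthesis had none of 46 called and a median of -0.39 (set test downward, 0.00474, and adjusted p = 0.802 with an estimated correlation). Endosperm had none of 4 called (2 higher adjusted over the list alone) with a median of 0.66 (set test 0.0151, and adjusted p = 0.636 with an estimated correlation). No embryo maturation regulator passed (FUS3 was at -0.51, adjusted p = 0.0783; 1 lower adjusted over the list alone), and fatty acid synthesis, cell cycle, abscisic acid, gibberellin (1 lower adjusted over the list alone) and seed coat lists held no calls. Set tests of the lists that did not pass gave 0.0508 to 0.688.

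Pairing the libraries of day 7 by replicate number gave 1272 genes in place of 597, with 2 embryo maturation regulators higher and 3 lower, 6 storage protein genes higher and 1 lower, 2 LEA genes higher and 1 lower, and 1 seed coat gene higher and 2 lower. The blocked set tests gave adjusted p = 2.96e-08 for photosynthesis with 3 genes lower, 9.31e-05 for endosperm with 2 higher, 0.000284 downward for fatty acid synthesis with 1 lower and 0.0201 upward for lipid mobilisation with 2 higher, and no list passed with an estimated correlation, at 0.202 for endosperm and 0.406 for the other 3. Without wild-type replicate 2 the count was 384, in a fit on the 2 groups alone 107, without the 6 libraries with more ribosomal RNA 399, and with no filter on low values 1019. With no scaling 50.5% of 650 calls were higher, against 59.6%. Median, mean and set test differed in sign for the VAL and Polycomb, oil body, LEA and abscisic acid lists.

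At day 8, 391 genes were higher and 229 lower. AT1G02770 was higher by 5.64, AT5G16980 by 4.29 and GSTU26, a glutathione transferase, by 3.52 (SE 0.25, adjusted p = 3.82e-12), from 1.13 ± 0.15 in wild type to 18.3 ± 2.8 in val1. FLA7 was lower at -3.20, VAL1 at -2.24 and AT3G59210 at -2.20. SESA4 at 1.62 was the storage gene called, ATPXG2 at -1.25 the oil body gene (2 higher and 1 lower adjusted over the list alone), and PER1 at 2.07, XERO1 at 1.69 and AT3G17520 at -1.21 the LEA genes. CYP707A2 was higher by 0.88 and ABI2 lower at -0.67, RGL2 lower at -0.76, ICL higher by 0.85, COR15B higher by 1.64 and the zinc finger gene STZ lower at -1.44. Fatty acid and oil synthesis had none of 27 genes called and a median of -0.20 (set test downward, 0.0217, and adjusted p = 0.923 with an estimated correlation). VAL1 was the gene called in the VAL and Polycomb list, and no embryo maturation, photosynthesis, cell cycle, seed coat or endosperm gene passed. Set tests other than that for fatty acid synthesis gave 0.232 to 0.794. In a fit on the 2 groups alone 362 genes were called, and the VAL and Polycomb and LEA lists had a median and mean of different sign.

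At day 10, 646 genes were higher and 346 lower. AT2G31985, a gene of unknown function, was at 0.234 ± 0.15 in wild type and 23.4 ± 7.3 in val1, a log2 difference of 5.00 (SE 0.21, adjusted p = 3.92e-18). AT1G02770 was higher by 5.55 and AT5G16980 by 3.91. FLA7 was lower at -3.15, ILA at -3.0 and EM1 at -2.14 (SE 0.47, adjusted p = 0.00276). ILA was at 0.05 with only the reference form of its transcripts. CYP707A2 was higher by 2.77 (SE 0.20, adjusted p = 3.77e-12), FLC by 0.83, LEC1, a regulator of embryo identity, by 0.81 and GA2OX8 by 1.63, while ABI5 was lower at -0.87, ABI2 at -0.63 and RGL2 at -1.03. The Rubisco genes RBCS3B and RBCS1B were higher by 2.24 and 1.95, XERO1 by 2.14, AT2G25890 by 0.82 and ICL by 0.61. Of 33 cell cycle genes 1 was called, CYCB2;4 at 0.69 (4 adjusted over the list alone), with a median of 0.38 (set test 3.71e-06, and adjusted p = 0.962 with an estimated correlation). The LEA list had 1 higher and 1 lower (3 and 1 adjusted over the list alone), and storage, fatty acid, seed coat, endosperm and cold lists held no calls. Set tests other than cell cycle gave 0.622 to 0.935. With libraries paired by number 1630 genes were called in place of 992, with 11 cell cycle genes higher (set test 7.22e-09, and 0.0127 with an estimated correlation). Pairing also gave 4 LEA genes higher and 3 lower, 2 lipid mobilisation and 2 cold genes and 1 storage gene higher, and 1 fatty acid gene lower. Signs of median, mean or test differed for embryo maturation, storage, gibberellin and endosperm lists.

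At day 12, 986 genes were higher and 575 lower. AT1G02770 was higher by 5.21, AT3G05150 by 4.03 and FRO3, a ferric reductase, by 3.94 (SE 0.37, adjusted p = 1.04e-09), from 0.615 ± 0.46 to 16.0 ± 4.1. ILA was lower at -3.29, FLA7 at -2.84 and AT5G57910 at -2.43 (SE 0.26, adjusted p = 1.87e-08). ILA was at -0.01 with only the reference form of its transcripts. Of 33 cell cycle genes 17 were higher and none lower (25 and 0 adjusted over the list alone), with TSO2, a ribonucleotide reductase subunit, at 1.51 (SE 0.21, adjusted p = 2.67e-06), PCNA1 at 1.23, CDKB1;1 at 1.17 and MCM3 at 0.94. The cell cycle median was 0.76 (set test 7.88e-14, and adjusted p = 0.261 with an estimated correlation). The level of the list was low in both genotypes, with a mean log2(scaled FPKM + 0.5) of 0.205 to 0.369 in wild type and 0.744 to 1.27 in val1. CYP707A2 was higher by 2.29, and ABI2, AHG1 and ABA1 were lower at -1.01, -1.25 and -0.58 (1 higher and 5 lower adjusted over the list alone). NF-YB6 was higher by 1.5 (2 regulators higher adjusted over the list alone), FLC by 0.75, RBCS1B, RBCS3B and PETE1 by 1.59, 1.48 and 1.12 (2 adjusted over the list alone), GA2OX8 by 1.57, GASA4 by 0.87 and XERO1 by 1.59, while EM1 was lower at -2.09, RGL2 at -1.04, the sucrose synthase SUS3 at -0.81, PDAT at -0.58, KIN1 at -1.71 and KIN2 at -1.61. The LEA list had 2 higher and 2 lower adjusted over the list alone, and storage, oil body, lipid mobilisation, seed coat and endosperm lists held no calls. Set tests other than cell cycle gave 0.839 to 0.981. Without the 6 libraries with more ribosomal RNA, 2 of them of day 12, the count was 876 and 4 cell cycle genes were called with a median of 0.48, and 9 were called with a median of 0 in the second quantification. With no scaling it was 954 and in a fit on the 2 groups alone 993. Signs of median, mean or test differed for embryo maturation, VAL and Polycomb, lipid mobilisation, seed coat and endosperm lists.

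At day 13, 1969 genes were higher and 1291 lower. AT1G02770 was higher by 5.05, AXR3 by 5.00 (SE 0.32, adjusted p = 1.06e-13) and AT3G05150 by 4.76. The glutathione transferase gene GSTF9 was at 33.0 ± 11 in wild type and 2.85 ± 0.28 in val1, a log2 difference of -3.27 (SE 0.28, adjusted p = 1.01e-10). ILA was lower at -3.54, a value that was 0.18 with only the reference form of its transcripts, and the pyruvate kinase gene AT3G49160 at -2.65 (SE 0.42, adjusted p = 1.71e-05). Of 33 cell cycle genes 12 were higher (15 adjusted over the list alone), with TSO2 at 1.55, CDKB2;1 at 1.14, MCM3 at 0.82 and CDT1A at 0.78 (set test 0.000221, and adjusted p = 0.766 with an estimated correlation). Of 20 LEA genes 4 were lower, EM1 at -2.58, RAB18 at -1.99, AT3G17520 at -1.41 and AT3G15670 at -1.28 (set test 0.00568, and adjusted p = 0.766 with an estimated correlation). Of 46 photosynthesis genes 5 were higher (4 adjusted over the list alone), with PSBO2 at 1.67, ATPC1 at 1.40 and ATPD at 1.28 (set test 0.00568, and adjusted p = 0.958 with an estimated correlation). In lipid mobilisation LACS7 at -1.13 and MFP2 at -0.51 were lower (4 lower adjusted over the list alone; set test 0.0219, and adjusted p = 0.766 with an estimated correlation).

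Among regulators at day 13, NF-YB6 was higher by 2.99 (SE 0.40, adjusted p = 9.08e-07), FLC by 0.80 and CYP707A2 by 1.24, and ABI5 was lower at -1.03, ABI2 at -1.44, AHG1 at -2.10 and CYP707A1 at -1.14 (3 abscisic acid genes higher and 6 lower adjusted over the list alone, against 1 and 5). Gibberellin had 5 of 12 higher and 1 lower (6 and 2 adjusted over the list alone), with GA2OX8 at 1.84, GASA6 at 1.3, GA20OX1 at 0.83 and RGL2 at -1.04. CAC1 at 0.63, DGAT2 at 0.58, PDAT at -0.55 and SUS3 at -1.47 were the fatty acid and oil synthesis genes called, and PDAT was at 1.52 in the second quantification. OLEO3 at 1.01 and HSD5 at -0.64, MUM4 at 1.03, and COR47 at 1.15, HSP70 at -0.74 and LTI78 at -0.70 were called in the oil body, seed coat and cold lists, and no storage or endosperm gene was. These lists had set test adjusted p from 0.159 to 0.93, and the cell cycle list had 2 genes called and a median of 0 in the second quantification. The level of the cell cycle list was low, with a mean log2(scaled FPKM + 0.5) of -0.424 to -0.105 in wild type and -0.003 to 0.34 in val1. With libraries paired by number 5330 genes were called in place of 3260, and the blocked set tests gave 2.32e-06 for photosynthesis with 27 higher, 5.86e-06 for cell cycle with 17 higher, 0.000762 for LEA with 2 higher and 7 lower, 0.00438 for lipid mobilisation with 1 higher and 7 lower, and 0.00772 for fatty acid synthesis with 12 higher and 2 lower. With an estimated correlation these were 0.476 for photosynthesis, LEA and lipid mobilisation, 0.0587 for cell cycle and 0.512 for fatty acid synthesis. Pairing gave 2 embryo maturation regulators higher and 3 lower, 3 VAL and Polycomb genes higher and 1 lower, 1 oil body gene higher and 3 lower, 3 abscisic acid genes higher and 6 lower, 6 gibberellin genes higher and 2 lower, 2 seed coat genes higher, and 2 cold genes each way. The count was 1643 without wild-type replicate 2, 2032 without val1 replicate 1, 2106 without val1 replicate 3, 1536 in a fit on the 2 groups alone and 2108 with no scaling, where 75.1% were higher against 60.4%. Signs of median, mean or test differed for embryo maturation, VAL and Polycomb and endosperm lists.

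At day 15, 2207 genes were higher and 1039 lower. RGF2 was higher by 6.12 (SE 0.42, adjusted p = 5.73e-13) and AXR3 by 5.44, and both were listed at 0 in 2 of the 3 wild-type libraries. AT1G02770 was higher by 4.60. The ferritin genes FER1 and FER3, which encode iron stores of plastids, were at 32.9 ± 12 and 14.5 ± 1.4 in wild type and at 2.34 ± 0.28 and 0.985 ± 0.33 in val1, differences of -3.49 (SE 0.47, adjusted p = 1.51e-06) and -3.36 (SE 0.37, adjusted p = 3.19e-08). ILA was lower at -4.58, and at -0.26 with only the reference form of its transcripts. Of 15 embryo maturation regulators 4 were higher and none lower (4 adjusted over the list alone; set test 0.28): NF-YB6 by 2.90 (SE 0.40, adjusted p = 1.88e-06), ABI4 by 0.94, AGL15 by 0.89 and FUS3 by 0.64. Of 27 fatty acid and oil synthesis genes 6 were higher (12 adjusted over the list alone), with the sucrose synthase SUS2 at 2.59, ROD1 at 1.59, LPD1 at 1.26 and KCR1 at 0.67 (set test 0.00138, and adjusted p = 0.93 with an estimated correlation). Among LEA genes M17 was higher, and EM1 at -1.57 and HSP101 at -0.61 were lower (3 lower adjusted over the list alone; set test downward, 0.0359, and adjusted p = 0.93 with an estimated correlation). Gibberellin had 6 of 12 higher, with GA2OX8 at 2.53, GASA6 at 1.88, GA20OX2 at 1.5 and RGA1 at 0.74 (set test 0.0581).

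At day 15 abscisic acid had 5 of 19 higher and 3 lower, with the receptor PYR1 at 1.02, ABA2 at 0.77, ABI1 at -0.74 and AAO3 at -0.71. Cold and handling had 4 of 15 higher and 1 lower (5 and 2 adjusted over the list alone), with the touch genes TCH2 and TCH4 at 2.07 and 1.94 and WRKY40 at 1.52. Photosynthesis had 4 higher and 1 lower (3 and 1 adjusted over the list alone), with RBCS1A at 2.12, PSBR at 1.84 and LHCB4.1 at -1.12, and cell cycle 1 higher and 3 lower, with CDT1A at 0.98 and PCNA2 at -0.74. FLC at 0.56 and CLF at 0.66 were higher in the VAL and Polycomb list (3 higher and 2 lower adjusted over the list alone), MUM4, F3H and TTG2 at 0.78, 0.99 and 0.52 in the seed coat list, AT4G36700 at 1.08 in the storage list and OLEO3 at 0.97 in the oil body list (0 adjusted over the list alone), and no lipid mobilisation or endosperm gene was called. Set tests of the lists in this paragraph gave 0.0939 to 0.869. The count of day 15 was 1948 without wild-type replicate 2, 2105 without val1 replicate 1, 1738 without val1 replicate 3, 689 in a fit on the 2 groups alone and 2123 with no scaling, where 84.2% were higher against 68.0% and the median of all genes was 0.11. Without val1 replicate 2 the count was 4475. Signs of median, mean or test differed for storage, cell cycle, abscisic acid and seed coat lists.

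At day 17, 1844 genes were higher and 1026 lower, with 2 wild-type and 3 val1 libraries. AT3G19800, a gene of unknown function, was at 0.424 ± 0.4 in wild type and 33.1 ± 8 in val1, a log2 difference of 5.23 (SE 0.28, adjusted p = 2.03e-15). The neighbouring near copies of TPS-CIN, a terpene synthase that makes cineole, were higher by 5.26 (AT3G25820, adjusted p = 2.99e-11) and 5.21 (AT3G25830, adjusted p = 2.47e-11), values that are uncertain for each copy because reads can be shared. ILA was lower at -5.47 (SE 0.29), and at -0.31 with only the reference form of its transcripts. HDA3, a histone deacetylase of the plant-specific class, was at 32.3 ± 4 and 3.37 ± 0.79, a difference of -3.10 (SE 0.37, adjusted p = 1.96e-07), and the ribosomal protein gene AT5G18790 at -2.58 (SE 0.30, adjusted p = 1.39e-07). CRU3 stood at 8.44e+04 in wild type and 2.11e+05 in val1, and storage protein genes took 24.4 ± 3.16% (n = 2) and 39.6 ± 8.29% of the reads.

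Embryo maturation regulators were higher in val1 at day 17 in 9 of 15 cases and lower in none (9 and 0 adjusted over the list alone), with set test adjusted p = 1.1e-05, and 0.00817 with an estimated correlation. With no scaling 4 were higher and 0 lower, with a median of 0.297, and the second quantification gave 6 higher and 1 lower. AGL15, a MADS-box factor of embryos, was higher by 1.90 (SE 0.21, adjusted p = 3.59e-08), FUS3, a B3-domain activator of seed genes, by 1.53 (SE 0.18, adjusted p = 1.12e-07), DPBF2 by 2.74 (SE 0.33, adjusted p = 2.28e-07) and WRI1, an activator of oil synthesis genes, by 1.96 (SE 0.27, adjusted p = 2.84e-06). NF-YB6 was higher by 1.5, DOG1, a seed dormancy gene, by 1.17, BBM by 1.03, ABI3 by 0.67 and ABI4 by 0.62, with adjusted p from 0.00161 to 0.0484. LEC1, LEC2, ABI5, EEL, HSFA9 and MYB118 did not pass. Fatty acid and oil synthesis had 13 of 27 higher (13 adjusted over the list alone), with KCS18 at 4.37 (SE 0.47, adjusted p = 2.88e-08), FAD3 at 2.83, FAB1 at 2.09 and FAD2 at 1.92 (set test 1e-05, and adjusted p = 0.776 with an estimated correlation). Storage proteins had 3 of 13 higher (5 adjusted over the list alone), SESA2 by 2.58, SESA4 by 2.53 and SESA3 by 1.79 (set test 0.00408, and adjusted p = 0.776 with an estimated correlation). From day 12 to day 17 in wild type these lists had 9, 24 and 6 genes falling and 2, 2 and 1 rising. At day 17 val1 lay at -0.684 days on the wild-type time course (exact permutation, one-sided p = 0.1). No correction for position was made for these lists, so a younger stage was not separated from other effects of the mutation.

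In the VAL and Polycomb list of day 17 FIE at 0.81, FLC at 0.63 and HSL1 at 0.54 were higher, and VAL1, VAL3 at -0.77 and TFL2 at -0.45 lower. Abscisic acid had 5 of 19 higher and 2 lower (6 and 2 adjusted over the list alone), with NCED9, of abscisic acid synthesis, at 1.61, HAI1 at 1.60, PYL1 at 0.67 and ABI1 at -0.92. GASA6 at 1.98 and RGA1 at 0.58 were higher in the gibberellin list, PETC at 1.73 and PSBR at 1.57 in photosynthesis (1 adjusted over the list alone), TCH2 at 2.33, TCH4 at 1.58 and WRKY40 at 1.25 in cold and handling (4 adjusted over the list alone), MUM4 at 0.81 in seed coat (0 adjusted over the list alone), and PCNA2 was lower at -0.98 in cell cycle. No oil body, LEA, lipid mobilisation or endosperm gene was called, and set tests of the lists other than the 3 that passed gave 0.128 to 0.957. The count of day 17 was 1583 without wild-type replicate 1, 1698 without wild-type replicate 2, 1790 without val1 unnumbered library 3 and 1284 in a fit on the 2 groups alone. With no scaling 24.7% of 2626 calls were higher, against 64.2%, and the median of all genes was -0.24. Signs of median, mean or test differed for VAL and Polycomb and seed coat lists.

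**Figure D3:**
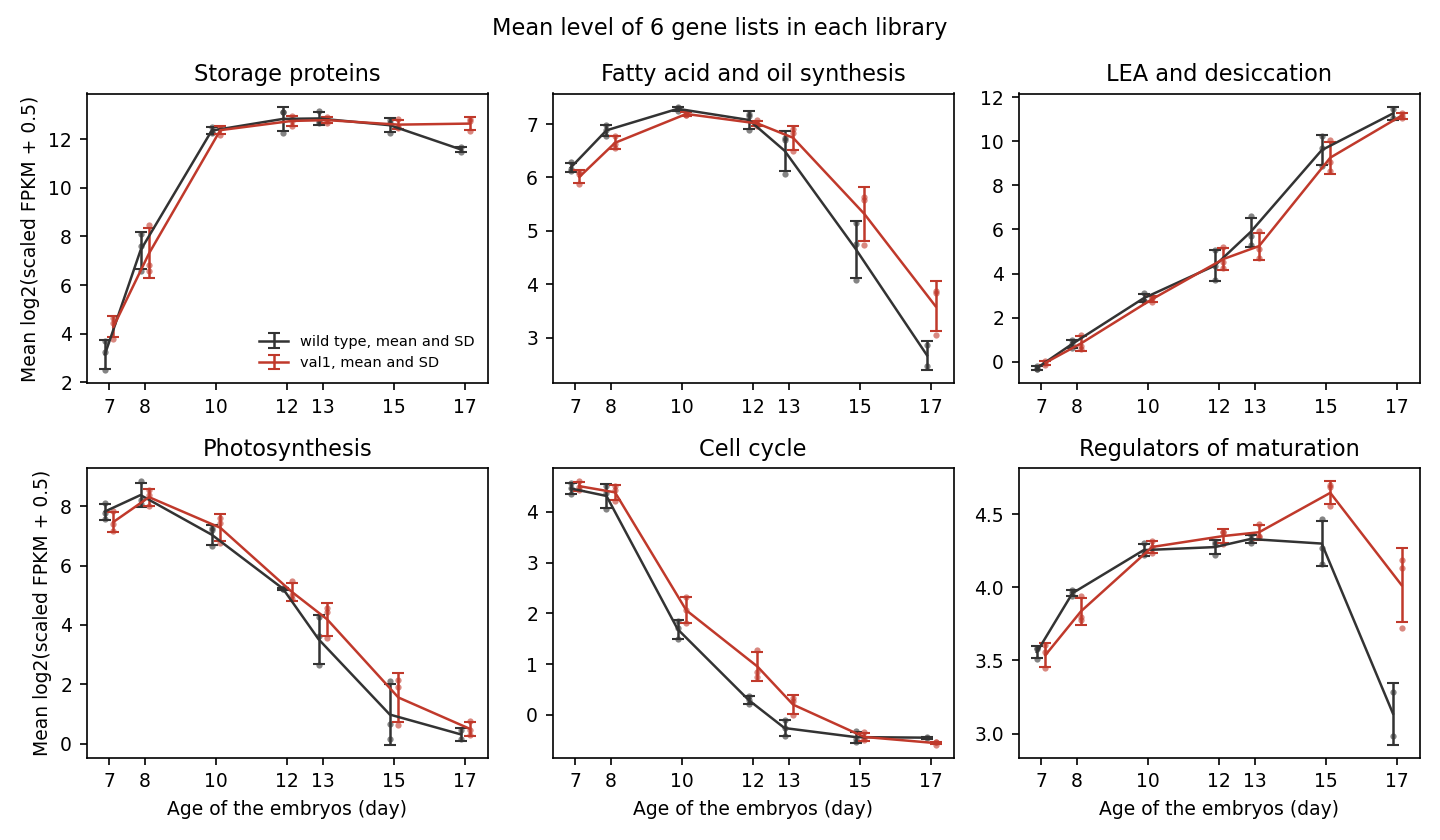
Mean log2(scaled FPKM + 0.5) of the members of 6 fixed lists by age in days, with a point per library and lines and bars for the group mean and SD in wild type and val1. At day 17 the embryo maturation regulators stood at 3.14 in wild type and 4.01 in val1, and the storage proteins at 11.58 and 12.64.

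A test of the interaction asks whether the difference between genotypes depended on age, and 3083 genes passed it, against 1623 with the second quantification and 1280 in the 34 numbered libraries, which cover 6 ages. BZIP61, a bZIP transcription factor, had the smallest adjusted p at 6.29e-15: in wild type it went from 6.85 at day 7 to 0.468 at day 12 and in val1 from 7.85 to 10.4, so the log2 difference was 0.19 at day 7, 3.49 at days 12 and 13 and 0.03 at day 17. MEE48 (adjusted p = 1.58e-14) was listed at 0 in every wild-type library except 1 of day 8, and reached 6.0 ± 0.62 at day 10 and 6.49 ± 1.4 at day 12 in val1. GLTP2, a glycolipid transfer protein (3.15e-14), was listed at 0 in wild type at days 7, 10, 12 and 17 and stood at 24.6 ± 4.7 in val1 at day 13. The DUF295 gene AT5G03390 (1.55e-13) was at 1.96 ± 0.25 in wild type at day 7. AT4G08869, a putative membrane lipoprotein (1.55e-13), stood at 55.3 ± 33 in val1 at day 13, and the methyltransferase gene AT5G66430 (1.82e-13) at 14.1 ± 2.2 in val1 at day 17.

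The change from day 7 to day 12 differed between genotypes for 374 genes, 234 with a larger value in val1 and 140 with a smaller one. Storage proteins had 3 of 13 smaller (5 adjusted over the list alone; set test 7.22e-07, and adjusted p = 0.526 with an estimated correlation) and cell cycle 3 of 33 larger (10 adjusted over the list alone; 4.75e-13, and adjusted p = 0.309 with an estimated correlation). The change from day 12 to day 17 differed for 2047 genes, 1149 larger and 898 smaller in val1. Embryo maturation regulators had 5 of 15 larger (7 adjusted over the list alone; set test 0.000125, and 0.0291 with an estimated correlation), fatty acid and oil synthesis 7 of 27 (12 adjusted over the list alone; 5.67e-06, and adjusted p = 0.554 with an estimated correlation) and storage proteins 3 of 13 (0.00418, and adjusted p = 0.696 with an estimated correlation). The remaining lists gave 0.0695 or more for the first interval and, leaving aside cell cycle, 0.0615 or more for the second. Cell cycle had 10 of 33 smaller in the second interval (1 larger and 20 smaller adjusted over the list alone; 2.26e-10, and adjusted p = 0.28 with an estimated correlation).

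**Figure D4:**
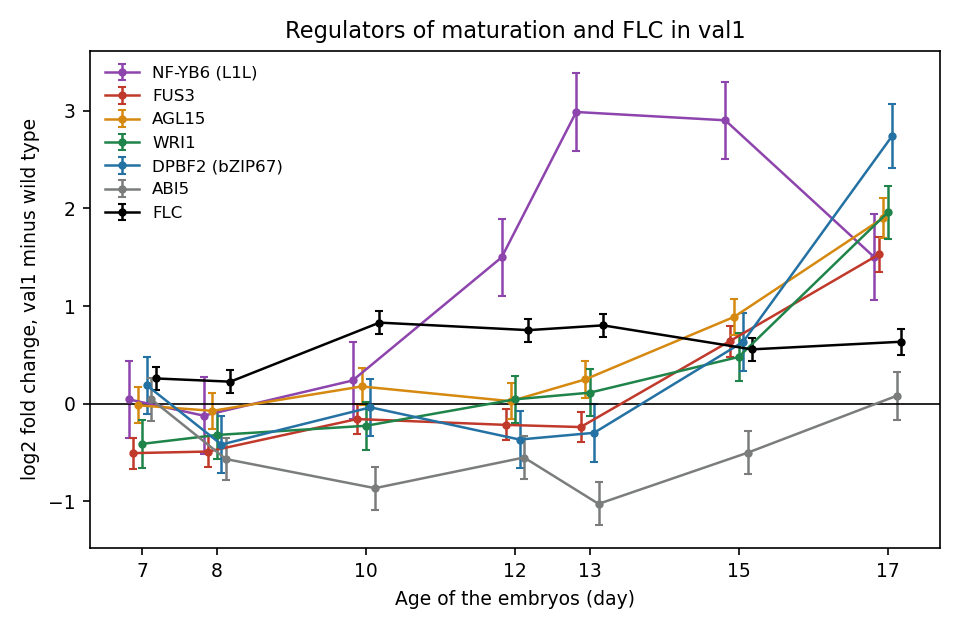
Log2 difference, val1 minus wild type, of NF-YB6, FUS3, AGL15, WRI1, DPBF2, ABI5 and FLC by age in days, with bars for the SE. FUS3 was at -0.51 at day 7 and 1.53 at day 17, and NF-YB6 at 2.99 at day 13.

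The authors deposited a table of 7826 transcripts that passed their own test over the 7 days, and it allows the calls to be set side by side. It holds transcripts of 4949 of the genes tested here, of which 4677 (94.5%) were also called on at least 1 day here, among 6002 genes called on any day. Across those genes, which are not independent replicates, the deposited and recomputed log2 differences correlated at 0.843 to 0.898 per day. The table lists 2 transcripts of VAL1, with differences of -3.24 and -2.82 at day 7 and of -2.01 and -0.97 at day 17.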

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

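Of the tests in this part, the position test over days 12, 13 and 15, the share of higher genes and the level of the cell cycle list with no scaling were chosen only after the result was seen; the reading of the gap between rising and falling genes was also settled after it.

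The difference between val1 and wild type depended on age for 3083 genes by the interaction test of limma (1623 with the second quantification), the change from day 7 to day 12 differed between genotypes for 374 and that from day 12 to day 17 for 2047. Among named genes the interaction adjusted p was 6.29e-15 for BZIP61, 1.58e-14 for MEE48, 3.15e-14 for GLTP2, 1.55e-13 for AT5G03390 and for AT4G08869, and 1.82e-13 for AT5G66430. Of the genes higher on average, it was 3.1e-10 for ADF5, 1.56e-09 for AT3G05150, 2.16e-08 for RGF2, 5.68e-08 for AXR3, 1.26e-07 for AT5G16980, 3.97e-07 for AT5G17000, 1.88e-05 for AT5G60250, 0.00199 for AT5G02230 and 0.00329 for AT4G04760. Of the genes lower on average, it was 1.07e-10 for ILA, 0.000307 for VAL1, 0.000622 for FLA7, 0.00496 for AT3G59210, 0.0259 for AT1G36070 and 0.0302 for AT3G10300. Outside the genes tested, 251 of 894 left-out transcripts differed between genotypes on average, 132 higher and 119 lower in val1, a signal in data that the comparisons did not use.

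Over days 12, 13 and 15 the libraries of val1 lay at younger positions of the wild-type time course, with a mean of -0.57 days relative to wild type (exact permutation within days, one-sided p = 0.00438). Each of these days alone gave an exact one-sided p of 0.1. The permutations in this paragraph exchanged libraries freely within a day and took no account of the pairs on days 10 and 13. Day 17 was at -0.684 days (exact p = 0.1), and days 8 and 10 together at -0.161 (exact p = 0.155), so a start of the difference at day 12 was not shown. Scaling is argued against as the whole source, since with no scaling the difference was -0.502 days (exact permutation, one-sided p = 0.0329, two-sided 0.0658). A younger age at collection stays open, although the bound set for it was met: rising and falling genes differed by 0.184 days (exact two-sided p = 0.0328). That bound was wrong by design, because differences between genotypes that have nothing to do with age add to the position from either gene set, and both sets gave a difference below 0, -0.44 days from rising (exact one-sided p = 0.0286) and -0.624 from falling genes (p = 0.00338). Slower development and younger embryos at collection cannot be told apart here, because no measure of age other than the day in the label was used.

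Of the 122 genes with a mean log2 CPM of at least 1 that differed by at least 2-fold on average and in the same direction on all 7 days, 98 (80.3%) were higher in val1, among them AT1G02770, AXR3, RGF2 and ADF5, against 61.3% of all 5895 genes called on average. The 5895 had no minimum difference, abundance or sign condition, so these shares are not like for like. Sequence differences close to VAL1 in the mutant line are argued against, since 0 of the 122 genes lay within 50 neighbours of VAL1 (median 1 and 95th percentile 2 in 10000 random sets). A wider stretch was not tested. Without the 6 libraries with more ribosomal RNA 100% of the genes kept their call and sign. Genes picked for a call and the same sign on all 7 days could hardly lose either, so this decides little about those libraries. Loss of a repressor stays open: the share of 80.3% is the pattern itself, seen before its bound was set, and genes that change together are not independent. Whether VAL1 acts on these genes was not tested.

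The cell cycle list was higher in val1 on days 10, 12 and 13 by the set test with the preset correlation, with 1, 17 and 12 of 33 genes called. The differences of days 12 and 13 lay between low levels. On the log2(scaled FPKM + 0.5) scale the wild-type list mean was 4.35 to 4.57 at day 7. At day 12 it was 0.205 to 0.369, against 0.744 to 1.27 in val1. At day 13 it was -0.424 to -0.105, against -0.003 to 0.34 in val1. Unpaired, no call held with the estimated correlation (adjusted p = 0.962, 0.261 and 0.766). With libraries paired by number it was 0.0127 at day 10 with 11 genes called, which passed, and 0.0587 at day 13 with 17. Younger position, as estimated from genes outside the lists, is argued against as the whole source on days 10, 12 and 13. This takes each estimated position as exact. Differences between genotypes unrelated to age can shift it, so a lag larger than estimated stays open. The wild-type list mean was 4.05 to 4.51 at day 8 and 1.49 to 1.86 at day 10, so a small error in position moves the outcome. After subtraction of the wild-type level at each library's position, the list mean stayed higher in val1 by 0.284, out of a difference of 0.50. The exact permutation within days gave a one-sided p = 0.000125, the smallest it can give. These days were picked because the list was higher there in the same libraries, and permutations over them ignore that choice. Within each of them every val1 library lay above every wild-type one, at day 12 with 0.175, 0.202 and 0.62 (unnumbered) against at most 0.163. At day 17 every val1 library lay lower (-0.097, -0.14 and -0.097 against -0.025 and 0.021), and on the remaining days the genotypes overlapped. Scaling is argued against, since with no scaling the list mean was higher by 0.485 (exact permutation, one-sided p = 0.00025). The level of the list relative to all genes decides nothing about scaling, because a factor moves both alike. Without the 6 libraries with more ribosomal RNA 4 genes were called at day 12, and in the second quantification the list median was 0 on days 12 and 13, so the libraries and the quantification stay open as part of the size. No biological explanation of the remaining difference was tested.

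Other splits of the same libraries mix the genotypes or ages. They can carry part of a real difference and add the rest to the spread within groups, so they give no count free of it. For the average, 1 of 100 splits, the real one, gave 5895 genes or more (highest other 660), and for the interaction 1 of 100 gave 3083 or more (highest other 2187). Labels drawn at random within days thus reached the real count in a share under 0.05 for both. Draws that swap genotypes on some days only can turn a steady difference into interaction calls, so 2187 is not a count due to chance alone. The single days have 10 splits each, too few for a share under 0.05: the real and the highest other value were 620 and 279 at day 8, 992 and 4 at day 10, 1561 and 52 at day 12, 3260 and 333 at day 13, and 3246 and 2827 at day 15. For development they were 13747 and 190 in wild type from day 7 to day 12, 13693 and 1 in val1 from day 7 to day 12, and 13789 and 1 in val1 from day 12 to day 17, also with 10 splits. Splits that mix ages raise the spread within groups for the many genes that change, so the low counts of the development splits decide nothing. At day 7, 2 of the 10 splits gave 597 genes or more, and the other one, val1 replicates 1 and 3 with wild-type replicate 3 against the rest, gave 1316 and points to a structure of the samples that follows the replicate numbers; with the numbers as a block the count was 1272. Where numbers pair the libraries, 4 of the 10 splits part all 3 numbers, and those other than the real one gave 0, 2 and 2 genes at day 7 and 0 at days 10 and 13. At day 15 the 3 other splits that part all numbers gave 0 too, and the split with 2827 genes parts 1 number.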

How the results depend on the processing

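Of the alternatives in this part, no scaling, other pseudocounts, reference-structure transcripts, the second quantification, leaving out the 6 libraries with more ribosomal RNA, the 34 numbered libraries and scaling without seed protein genes were chosen only after the data were seen. Of 617 log2 differences of 240 named genes under these settings, 8025 values kept direction and side of the threshold, 450 kept direction alone and 25 changed sign; with 1 library left out the numbers were 5721, 251 and 0. The cause of a change was not tested unless given.

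With a minimum log2 difference of 1, which leaves fewer genes by construction, counts were 223, 285, 457, 598, 1079, 1174 and 1216 on days 7, 8, 10, 12, 13, 15 and 17, 341 on average, 7996 and 8701 for wild type and 7791 and 8530 for val1 from day 7 to 12 and from day 12 to 17. A fit on the 2 groups alone, with fewer samples, gave 107, 362, 993, 1536, 689 and 1284 on days 7, 8, 12, 13, 15 and 17. The second quantification gave 319, 270, 466, 784, 1499, 1563 and 1388 on the 7 days, 2823 on average and 1623 for the interaction. No scaling gave 954, 2108 and 2123 on days 12, 13 and 15, no filter 1019 on day 7, and the libraries without the 6 with more ribosomal RNA 876 on day 12. The 34 numbered libraries gave 397 and 855 on days 8 and 12 and 1280 for the interaction, over 6 ages without day 17.

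The replicate block within day gave 1272, 1630 and 5330 on days 7, 10 and 13, where numbers pair the libraries, and changed no other set test call there than those given with these days. On the other days the numbers did not meet the rule for pairs, which asks for 3 pairs above 0.1. Same-number correlations were 0.563 and 0.448 on day 8, 0.129 and 0.231 on day 12, and 0.0743, 0.591 and 0.555 on day 15, where val1 replicate 1 correlated best with wild-type replicate 3 (0.351). This block gave 5286 on day 15, and a block over all days 928 on day 12 and 1580 for the interaction over 6 ages.

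With 1 library left out counts ran from 384 to 681 on day 7, 447 to 559 on day 8, 690 to 898 on day 10, 1078 to 1413 on day 12, 1643 to 3449 on day 13, 1738 to 4475 on day 15, 1583 to 3359 on day 17, 5296 to 6307 on average and 2292 to 4093 for the interaction. From day 7 to 12 they ran from 13047 to 13333 in wild type and 13019 to 13216 in val1, and from day 12 to 17 from 12088 to 13149 and 13128 to 13384. A group left with 1 library was taken to vary like the others. On day 7 the count was 384 without wild-type replicate 2; on day 13, 1643 without wild-type replicate 2, 2032 and 2106 without val1 replicates 1 and 3; on day 15, 1948 without wild-type replicate 2, 2105 and 1738 without val1 replicates 1 and 3; on day 17, 1583 and 1698 without wild-type replicates 1 and 2 and 1790 without val1 unnumbered library 3.

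Signs changed as follows. With reference-structure transcripts ILA was 0.052 on day 10 and 0.18 on day 13. DPBF2 was -0.045 on average with either replicate block and in the 34 numbered libraries, which average 6 ages without day 17. With no scaling, which moves all genes, the change from day 7 to 12 in wild type was -0.421 for FUS3, -0.781 for AGL15, -0.764 for ABI4, -0.612 for HSL1, -0.651 for VAL1, -0.726 for SWN, -0.873 for EMF2 and -0.396 for MFP2; in val1 it was -0.007 for FUS3, -0.295 for WRI1, -0.451 for ABI4, -0.617 for AGL15, -0.475 for HSL1 and -0.68 for SWN, and from day 12 to 17 it was -0.071 for ABI3 and -0.111 for FLC. In the second quantification SWN was -1.193 and EMF2 -0.854 from day 7 to 12 in wild type, PDAT 1.52 on day 13 and CYP707A2 -0.033 on average.

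With the estimated correlation 41 set test calls of the daily, average and development contrasts were lost and 127 results kept their side of the threshold. Calls lost in the differences of intervals between genotypes are not in this number and are given with those differences. A second count-based tool named in the plan was not run, because the recovered reads were not whole. The lowest estimated depth was 8321306 reads, in a val1 library of day 7, against a median of 29731894.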

Other observations

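The keyword groups in this part were chosen only after the data were seen, and 189 one-sided Fisher's exact tests were run on them.

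Among genes higher in val1 on average, 134 of 364 ribosomal protein genes were found where 71.5 would fall by their number (adjusted p = 1.96e-12), and 41 were among the genes higher at day 12 where 19.5 would fall (0.00037). Among genes lower on average, 50 of 150 F-box genes were found where 18.6 would fall (1.82e-09). Thionin and defensin genes were among the higher genes in 13 of 25 cases (0.00952), pectin enzymes in 35 of 103 (0.0101) and xyloglucan enzymes in 9 of 16 (0.0224). On single days, 8 of 58 lipid transfer protein genes were higher at day 7 (0.00071), 19 of 90 cytochrome P450 genes were higher at day 17 (0.0224) and 8 of 40 glutathione transferase genes were lower at day 17 (0.0224). Genes are not independent replicates, and members of these families can share reads.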
